A study of Mus musculus with 18 samples.

How the data were processed

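The series measured m6A in mouse 3T3-L1 cells by antibody enrichment of RNA fragments followed by sequencing (m6A-seq). Per the labels' protocols, messenger RNA was selected by its poly(A) tail, depleted of ribosomal RNA, broken into short fragments and bound by an m6A antibody, and libraries were read from one end on an Illumina instrument. The 18 samples were an IP and an input for days -2, 0, 2, 5 and 10 of adipogenesis, and for siCtrl and siFTO cells with 2 replicates each. The list names matched the labels, which gave each of the 9 peak lists its group. The first siCtrl and siFTO samples carry no replicate number in the labels and are called replicate 1.

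Reads were aligned with TopHat2 2.0.9 to mm10 and handled with bedtools, per the submitters' processing notes. Each list belongs to one library pair, an IP and its input, so peaks were called per sample and not on pooled replicates. The peak caller, its thresholds and the scaling for depth are not given in the sources used here. Per the file headers, the deposited value of each peak is an enrichment computed by the authors. It was read here as a fold (ratio) of the IP over the input, since its formula is not given in the sources used here. Each peak also has a chromosome, a start and an end, the Ensembl gene, and its transcript part (5' UTR, coding sequence, 3' UTR or intron), all as deposited. An exon class with no part is found in the replicate 2 lists alone, with 0.741% of peaks in siCtrl 2 and 0.883% in siFTO 2. Lines for the mitochondrial genome had shifted cells and no fold, so they were set apart.

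Read depth is unknown, and no count per peak was used, so no count model was fitted and the precision of single folds is not known. Shares of peaks within one list have exact Clopper-Pearson 95% intervals, which cover counting error only. Coordinates are mm10 and are printed counting from 1. Of 12634 gene IDs, 12492 had a symbol. Of 338246 peaks, 327148 matched a RefSeq gene (assembly GRCm38.p6) of the same symbol and chromosome, and 98.2% of these had their midpoint inside it. The siCtrl lists held 17581 peaks at identical positions, of which 168 had the same fold, so the lists were used as separate samples.

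Peaks of all lists were merged into regions where they shared at least 1 base, and adjoining peaks stayed apart. The regions had a median length of 125 bases and the longest had 4325. A region or gene was gained when both siFTO lists and neither siCtrl list held it, and lost in the reverse case. The same counts were made for pairs that mixed the conditions. Peak number, genes, peaks per gene, median peak width, the share of adjoining peaks and the share in each part were compared between siFTO and siCtrl. The test was a two-sided exact permutation over the 6 assignments of 4 lists to 2 groups. An adjoining peak here is one that starts where the gene's previous peak ends, so the first of a run is not counted. The Jaccard index within against between conditions was compared over the 3 splits into pairs, one-sided. The smallest p of either is 0.333. The 10 measures had Benjamini-Hochberg adjusted values beside them. Stages have 1 list each, so counts are given without p-values.

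The 12 gene lists were adipogenic transcription factors, inhibitors of adipogenesis, mature adipocyte lipid genes, preadipocyte and extracellular matrix genes, cell cycle and DNA replication genes, m6A writers, erasers and readers, SR proteins and splicing factors, Wnt, BMP and TGF-beta signalling genes, cytosolic ribosomal protein genes, oxidative phosphorylation genes, immediate early and stress genes, and markers of macrophages, endothelium and muscle. They were fixed in advance, as were the naming rule and the results on peak number, Jaccard index, 3' UTR share, gained and lost regions, stage regions and list presence. The other measures, with the 5' UTR and intron shares and the counts of genes, were added after the peak lists had been examined. A list's mean difference in presence was placed among 10000 random lists of the same size, matched on the number of lists with a peak, and the limits were percentiles 2.5 and 97.5. This describes these libraries, since genes are not replicates. A score of peak number (1 for more peaks in both siFTO lists than in either siCtrl list, -1 for fewer) was added after the peak lists had been examined.

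Genes were named by rule. These were the m6A writers, erasers and readers with a peak, Fto first, and the 10 best genes gained and lost in siFTO. Likewise 10 were taken from late stages only, 10 from early stages only and 10 with a peak in all 9 lists. Genes were ordered by the worse of their fold percentiles, and genes without a proper name were left out. Up to 4 examples per gene list and comparison, Runx1t1, Pparg, Cebpa, Cebpb and Cebpd completed the rule. Genes outside it are said to be named after their values were seen.

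The counting of regions and the list percentiles were tested on simulated data. Of 50512 simulated regions, 200 of 200 seeded gained regions and 200 of 200 lost ones were recovered. The seeded regions were given the exact pattern without noise, so full recovery was fixed and checks the counting code alone. With 6000 simulated genes, 5.0% of lists without a shift fell outside the limits, and 77.0% of lists shifted by 0.5 lay above 97.5. Evenly spaced folds were sought in each list as the spacing whose whole multiples, within the rounding of the files, held the largest excess share of intronic folds above 5 over chance. Alternatives tried were peaks at or above each list's median fold, equal list lengths (the best peaks by fold), an overlap of 50% of each peak, presence per gene, each replicate left out, a replicate block, random lists without matching, leaving out the day -2 list or what it shares with siFTO, and leaving out peaks on evenly spaced folds. The labels mark the second siCtrl and siFTO samples alike as rep2, and the exon class is in these 2 lists alone, so they may share a batch. The labels do not say that same-numbered samples were made together, so the main values have no block.

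The consensus motif of m6A and the distance of peaks to exon junctions were not analysed here, because no genome sequence or exon map was used. The files give no stop codon class, so the 3' UTR share stands for the planned class of 3' UTR or stop codon. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.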

Results

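N6-methyladenosine (m6A), a methyl mark on adenosines of messenger RNA, was mapped in 3T3-L1 cells, a mouse embryo fibroblast line that turns into fat-storing adipocytes when it is induced to differentiate. RNA fragments bound by an m6A antibody (IP) were sequenced beside the fragments before binding (input), and the authors called peaks of the IP over the input. The series has 18 samples, an IP and an input for each of 9 conditions or replicates, which gave 9 peak lists. In the knockdown experiment, 2 lists came from control cells (siCtrl) and 2 from cells in which the m6A demethylase Fto was knocked down (siFTO). In the differentiation experiment, 1 list each came from days -2, 0, 2, 5 and 10 of adipogenesis. The stages had no replicates, so they were compared by counts and by placing gene lists among random lists, without p-values.

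The lists held 338246 peaks, which merged into 67750 regions on 12634 genes, and 5597 of these genes had a peak in all 9 lists. The stage lists held 26485 peaks on day -2, 37463 on day 0, 39852 on day 2, 44070 on day 5 and 44529 on day 10. The siCtrl lists held 35979 and 39133 peaks, and the siFTO lists 39476 and 31259, for replicates 1 and 2. Read depth is unknown, because the lists give a fold but no read count per peak. Intervals on shares of peaks are exact Clopper-Pearson 95% intervals and cover counting error only. The fold of IP over input is the authors' value for each peak, and it is used only to describe or rank peaks within one list. The lowest fold of every list was below 1, from 0.8 (siFTO 1) to 0.95 (day 10). A called peak therefore need not have a fold above 1, and the value may not be a plain ratio. In each list many high folds were whole multiples of one value, 27.6% (day 10) to 69.4% (siFTO 1) of the folds above 20. Chance gives 0.865% to 1.70% for a spacing fixed in advance. The spacing was instead chosen from the data, which raises the chance share by an amount not measured. Few input reads at a peak would give such evenly spaced folds, but no input counts were available. An order by fold may therefore favour peaks with little input, and their exact folds are uncertain. Nothing says that the replicates came from separate cultures, so the p-values measure only the spread between these samples.

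The targeted gene carried peaks in all 4 siRNA lists. Fto (ENSMUSG00000055932, chromosome 8, 91313367 to 91668433, mm10), which encodes an m6A demethylase, had 6 and 6 peaks in the siCtrl lists and 5 and 4 in the siFTO lists. An intronic peak at 91313526 to 91313625 and a coding peak at 91401801 to 91401875 were in both siCtrl lists and in neither siFTO list. Both siFTO lists held a coding peak at 91485151 to 91485250 that neither siCtrl list held. Fto had no peak on day -2, and 5, 4, 4 and 6 peaks on days 0, 2, 5 and 10. Peak number does not measure the level of Fto RNA, so the knockdown was not checked from these values.

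The comparison of siFTO with siCtrl asks where m6A peaks lie when a demethylase is depleted. In siFTO, peaks in 5' untranslated regions (UTRs) were scarcer, at 4.67% ± 0.479 (SD, n = 2) of each list's peaks against 11.6% ± 0.468 in siCtrl, and intronic peaks were more frequent, at 18.3% ± 1.65 against 11.4% ± 0.427. The intron difference was 2.44 points without peaks on evenly spaced folds. That cut removes intronic peaks by preference, since the spacing was chosen on intronic folds. Of 32 cell cycle and DNA replication genes, 6 were found in both siFTO lists and neither siCtrl list and none the reverse, at percentile 98.9 of random lists but at 95.3, inside the limits of 2.5 and 97.5, with equal list lengths. Of 23 immediate early and stress genes, 12 had fewer peaks in both siFTO lists than in either siCtrl list and 1 had more, past the limits also with equal list lengths (percentiles 0.13 and 0.59). Adjoining peaks each count in peak number, and they made up 11.2% of peaks in siFTO against 23.1% in siCtrl (means). Their part in this result was not tested. The siFTO lists named more genes, 9744.5 ± 554 against 8898 ± 266 (SD, n = 2), with fewer peaks on each, 3.62 ± 0.391 against 4.22 ± 0.125.

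Both the 5' UTR and the intron difference exceeded the spread between replicates. The 5' UTR share differed by -6.88 percentage points and the intron share by 6.96, each with p = 0.333 in a two-sided exact permutation test, which is the smallest p that 2 lists against 2 allow. Without peaks on evenly spaced folds the intron difference was 2.44 and the 5' UTR difference -6.58, and among peaks at or above the median fold they were 13.3 and -9.56. Of intronic folds above 5, 54.4% and 47.1% were evenly spaced in siFTO, against 16.9% and 19.9% in siCtrl. Of coding folds above 5, 12.1% and 8.32% were evenly spaced in siFTO, against 5.55% and 6.26% in siCtrl. The spacing was chosen on intronic folds, so leaving out these peaks lowers the intron share partly by construction. The 3' UTR share was 14.8% ± 1.04 in siFTO and 13.5% ± 0.258 in siCtrl (SD, n = 2), a difference of 1.36 points (exact permutation p = 0.333, two-sided), which was 0.626 without siFTO replicate 1 and 2.10 without siFTO replicate 2. The coding share was 61.7% ± 1.59 against 63.2% ± 0.741, with overlapping lists (exact permutation p = 0.667, two-sided). Peak number did not separate the groups, at 35367.5 ± 5810 in siFTO and 37556 ± 2230 in siCtrl (SD, n = 2; exact permutation p = 1, two-sided), and the difference of -2188.5 turned to 1920 without siFTO replicate 2. Over the 10 measures tested, the Benjamini-Hochberg adjusted value of each exact p of 0.333 was 0.476, so no measure could pass a threshold in this design. The day -2 list, which came from cells without knockdown, had 5' UTR and intron shares of 5.90% (95% interval 5.62 to 6.19) and 21.4% (20.9 to 21.9), nearer to the siFTO than to the siCtrl lists.

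**Figure D1:**
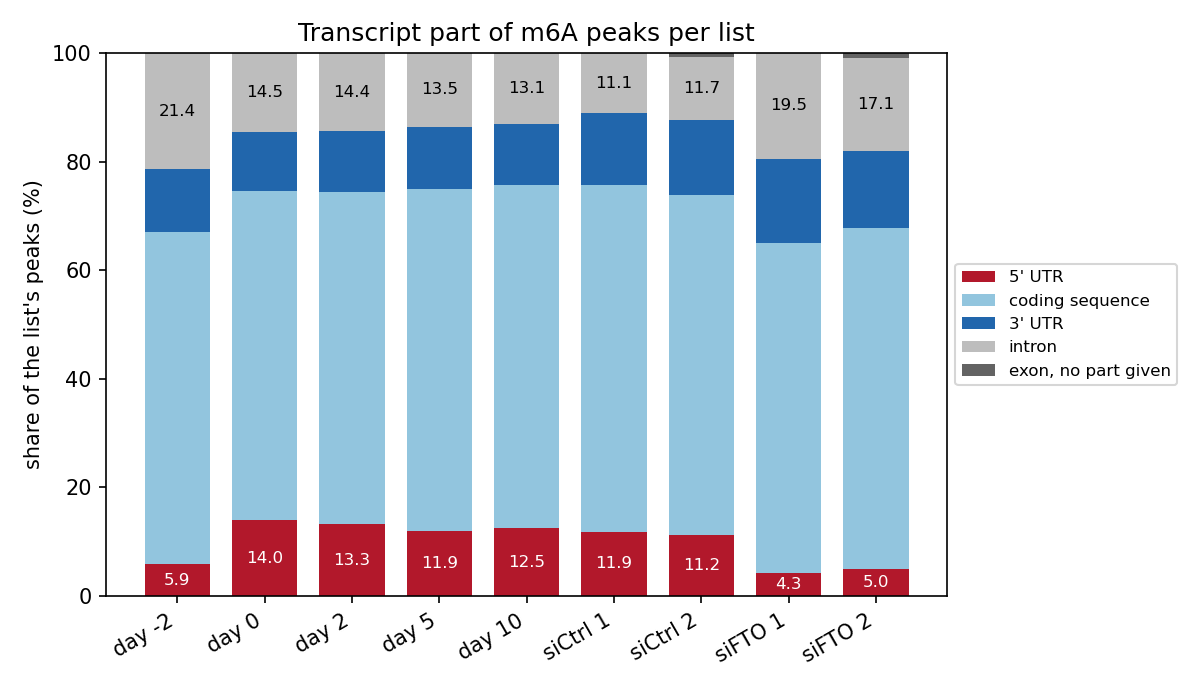
Share of each list's m6A peaks, in percent, by the transcript part the authors gave, with 1 bar for each of the 9 lists. The 5' UTR share is 5.90% on day -2, 4.33% and 5.01% in the siFTO lists, and between 11.2% and 14.0% in the other lists.

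Lists of one condition resembled each other more than lists of different conditions. The Jaccard index of shared regions was 0.812 for the siCtrl pair and 0.590 for the siFTO pair, against a mean of 0.432 between conditions. The mean within conditions exceeded the mean between them by 0.269, the largest of the 3 ways to split the lists into pairs (one-sided exact permutation p = 0.333, the smallest possible). This difference was 0.154 without siCtrl replicate 1 and 0.162 without siCtrl replicate 2. Of 47766 regions in the 4 lists, 14794 were in all 4, 5890 were in both siFTO lists only (gained) and 6949 in both siCtrl lists only (lost). Pairs that mixed the conditions held at most 615 such regions. Gained regions were intronic in 24.6% of cases and in a 5' UTR in 1.83%, whereas 22.2% of lost regions were in a 5' UTR and 13.1% were intronic. The day -2 list held 36.1% of the gained regions (95% interval 34.9 to 37.4), more than the 11.3% to 18.2% held by the lists of days 0 to 10. It held 15.5% of the lost regions (14.7 to 16.4), where the lists of days 0 to 10 held between 67.6% and 77.1%.

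By gene, 992 genes had a peak in both siFTO lists and neither siCtrl list, and 499 the reverse. More peaks in both siFTO lists than in either siCtrl list were found on 2484 of 11482 genes (21.6%), and fewer on 2762 (24.1%), where chance without ties gives 16.7% each way. Pairs that mixed the conditions gave at most 749 genes. Without siFTO replicate 2 the counts were 14286 gained regions, 1796 gained genes and 4725 genes with more peaks, and without siFTO replicate 1 they were 8899 gained regions, 974 lost genes and 4153 genes with fewer peaks. Leaving out what the day -2 list shared with siFTO kept 3761 gained and 1078 lost regions, and 436 gained and 171 lost genes, while peaks at or above the median fold gave 818 lost genes and an overlap of 50% of each peak gave 12077 lost regions.

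The 10 gained genes with the best fold rank in both siFTO lists were taken by a fixed rule, and all had a top fold in the highest 1% of both lists. The top folds of all 10 were evenly spaced in both siFTO lists, as they would be where input reads are few, though no input counts were available. Positions are those of the top siFTO 1 peak. Each fold is the gene's highest in its list, so siFTO 2 folds may lie elsewhere. Ntm (ENSMUSG00000059974), a neural cell adhesion gene, had its top peak in an intron at chromosome 9, 29941976 to 29942075, with folds of 207 in siFTO 1 and 384 in siFTO 2. Fbxo5 (ENSMUSG00000019773), an inhibitor of the anaphase-promoting complex, had a 3' UTR peak at chromosome 10, 5799351 to 5799500, with folds of 183 and 167. Depdc1a (ENSMUSG00000028175) had 4 and 2 peaks, the highest in the coding sequence at chromosome 3, 159522676 to 159522825, with folds of 113 and 203. Rps3a2 (ENSMUSG00000062611) had a coding peak at chromosome 14, 88123476 to 88123600, with folds of 130 and 95.5, and its reads may not be separable from those of the related ribosomal gene copies. The others were Zfp944, Rgs7bp and Sv2c, with top peaks in the 3' UTR, and Prepl, Ube2e2 and Avil, with top peaks in introns. Each of these 10 genes except Depdc1a and Rps3a2 also had a peak on day -2.

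The 10 lost genes named by the same rule mostly had coding peaks, with evenly spaced top folds for 10 in siCtrl 1 and 9 in siCtrl 2. Positions are those of the top siCtrl 1 peak. Each fold is the gene's highest in its list, so siCtrl 2 folds may lie elsewhere. Sptbn4 (ENSMUSG00000011751), which encodes a beta spectrin, had 3 and 3 peaks in the siCtrl lists, the highest at chromosome 7, 27364276 to 27364400, with folds of 40.1 and 47.2. Nova2 (ENSMUSG00000030411), a neuronal splicing regulator, had 1 peak at chromosome 7, 18957476 to 18957600, with folds of 43.8 and 34.9. Foxd2 (ENSMUSG00000055210), a forkhead transcription factor, had 3 and 3 peaks, the highest at chromosome 4, 114908551 to 114908700, and 8, 5, 4 and 6 peaks on days 0, 2, 5 and 10. Abhd15 (ENSMUSG00000000686) had a 5' UTR peak at chromosome 11, 77515026 to 77515150, with folds of 32.7 and 36.2. Adamtsl1 had 2 and 10 peaks, Shisa8 1 and 3, and Cilp2 3 and 3, while Pcdhb4 and Vwa1 had 1 in each siCtrl list. Rpl19-ps11, a pseudogene with folds of 111 and 105, may share reads with Rpl19. Adamtsl1 was the one gene of these 10 with a peak on day -2.

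Gene lists fixed before the data were examined were placed among 10000 random lists of the same size, as a percentile of their mean score, with limits at 2.5 and 97.5. Presence scores were matched on the number of lists with a peak. Scores of peak number were matched on mean peak number and were added after the peak lists had been examined. They were not matched on adjoining peaks, which each count as a peak and were scarcer in siFTO over all genes. Scores of peak number may therefore partly reflect how stretches were divided into peaks, which was not tested.

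Of the cell cycle and DNA replication genes, 6 were gained in siFTO (percentile 98.9 for presence), and 13 had more peaks and 5 fewer (percentile 98.9 for peak number). With equal list lengths the percentiles were 95.3 and 96.2, inside the limits. Bub1b (ENSMUSG00000040084), a spindle checkpoint kinase, had 3 and 3 peaks in siCtrl and 7 and 6 in siFTO. The highest in siFTO 1 was in the coding sequence at chromosome 2, 118622126 to 118622250. Top2a, the DNA topoisomerase of dividing cells, had 7 and 6 against 19 and 11 peaks, Rb1, which restrains entry into S phase, 1 and 2 against 4 and 4, and Ccne1 (cyclin E1) 1 and 1 against 3 and 2. Gained members were Ccne2, Aurkb, Cdc6, Aurka, Cdk1 and Mcm5, the last 2 named after their values were seen. The worse of their fold percentiles in the siFTO lists was 69.3, 40.2, 16.8, 11.9, 4.03 and 0.859, in that order. The list held 71 peaks on day -2 and 71 on day 0, against 87 and 76 in siCtrl and 133 and 100 in siFTO.

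Among ribosomal protein genes and splicing factors, too, members with more peaks in siFTO outnumbered those with fewer. Of 29 cytosolic ribosomal protein genes, 12 had more peaks and 1 fewer (percentile 99.8), among them Rpl4 (ENSMUSG00000032399) with 2 and 2 against 5 and 6, Rpl6 with 1 and 1 against 3 and 3, and Rps6 and Rps7 with none against 1 and 1. Presence was gained by 7 members and lost by Rpl18, named after its values were seen (percentile 86.1, or 98.3 without matching and 98.7 with equal list lengths). By the worse of their fold percentiles in the siFTO lists, Rps6 and Rps7 lay at 70.0 and 65.1. The other gained members lay at 0.0576 to 8.32, among the lowest folds of a list. The peak number call ended with equal list lengths (91.2). Reads of these genes may be shared with their many pseudogenes. Of 34 SR proteins and splicing factors, 11 had more peaks and 5 fewer (percentile 98.6; 96.1 without matching), including Hnrnpu (ENSMUSG00000039630) with 6 and 6 against 15 and 11, Srrm1 with 5 and 5 against 10 and 9, Rbm25 with 8 and 8 against 12 and 11, and Mbnl1 with 3 and 4 against 6 and 5. Hnrnpa1, Hnrnph1, Clk1, Srsf9 and Srsf5 were gained and no member was lost (percentile 85.5), Srsf5 being named after its values were seen. In that order, the worse fold percentile of these 5 in the siFTO lists was 30.8, 27.2, 12.7, 2.65 and 0.0816. On day -2 the ribosomal list held 36 peaks and the splicing list 113, each below every list of days 0 to 10. The whole day -2 list was shorter too, with 26485 peaks against 37463 on day 0. Its 36 ribosomal peaks lay above the 30 and 34 in siCtrl, and its 113 splicing peaks below the 151 and 152 in siCtrl.

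Immediate early and stress genes, which respond quickly to serum or stress, had the lowest peak-number percentile of the lists, 0.13 (0.59 with equal list lengths). Ier2 (ENSMUSG00000053560) had 6 and 5 peaks in siCtrl and 4 and 2 in siFTO. The highest in siCtrl 1 was in the coding sequence at chromosome 8, 84661989 to 84662159. Jund, an AP-1 subunit, had 4 and 4 against 1 and 1, and the heat shock genes Hspa1a and Hspa1b, near-identical copies whose reads may not be separable, had 4 and 5 against 2 and 2 and 6 and 6 against 3 and 3. Fos, lost from both siFTO lists, had 6 peaks in siCtrl 1 and 1 in siCtrl 2, and Atf3 was gained with 2 and 3 peaks, Fos being named after its values were seen. The list held 69 peaks on day -2, 114 and 92 in siCtrl, 78 and 60 in siFTO, and 157 to 177 on days 0 to 10.

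The lists of adipogenesis regulators lay inside the limits for peak number. Of 21 adipogenic transcription factors, 7 had fewer peaks and 1, Pparg, had more (percentile 9.27), with 102 and 104 peaks in siCtrl, 75 and 61 in siFTO and 53 on day -2. Zfp423 (ENSMUSG00000045333), a preadipocyte factor, had 9 and 11 against 2 and 2 peaks. The highest in siCtrl 1 was in the 5' UTR at chromosome 8, 87959314 to 87959450. Stat5b had 5 and 7 against 3 and 2, and Nr3c1, the glucocorticoid receptor, 12 and 12 against 9 and 7. Of 23 inhibitors of adipogenesis, 11 had fewer peaks and 3 more (percentile 4.19; 1.02 without matching), with 77 peaks on day -2. Notch1 (ENSMUSG00000026923) had 14 and 13 against 4 and 3 peaks, Irx5 6 and 7 against 3 and 3, Tgfb1 4 and 3 against 2 and 2, and Ctnnb1, which encodes beta-catenin, 2 and 2 against 1 and 0. Id2 was gained, and Dlk1, named after its values were seen, was lost.

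Cebpa (ENSMUSG00000034957, chromosome 7, 35119293 to 35121928), the transcription factor that maintains the adipocyte state, had 7 and 8 peaks over 1150 and 1200 bases in the siCtrl lists. In the siFTO lists it had 1 and 2 peaks over 200 and 300 bases, in the coding sequence and 3' UTR. Day -2 had 2 peaks over 225 bases, and days 0 to 10 had 8 to 10 peaks over 1475 to 1700 bases. Cebpd (ENSMUSG00000071637, chromosome 16, 15887286 to 15889545) followed the same grouping, with 825 and 575 bases in siCtrl, 100 and 175 in siFTO, 100 on day -2 and 975 to 1100 on days 0 to 10. Cebpb (ENSMUSG00000056501, chromosome 2, 167688915 to 167690432) had 950 and 825 bases in siCtrl, 625 and 550 in siFTO, 375 on day -2 and 1100 to 1225 later. Pparg (ENSMUSG00000000440, chromosome 6, 115360879 to 115490404), the master regulator of fat cells, had 3 and 2 peaks against 4 and 4, but the siFTO lists shared no intronic peak (115483126 to 115483225 in siFTO 1, 115481751 to 115481850 and 115485176 to 115485250 in siFTO 2), and 2 of the siFTO 1 peaks adjoin in the coding sequence. Runx1t1 (ENSMUSG00000006586, chromosome 4, 13742628 to 13895056), an inhibitor of adipogenesis, had 7 and 8 peaks in siCtrl and 11 and 8 in siFTO, with a 3' UTR peak at 13891576 to 13891700 in both siFTO lists and neither siCtrl list.

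**Figure D2:**
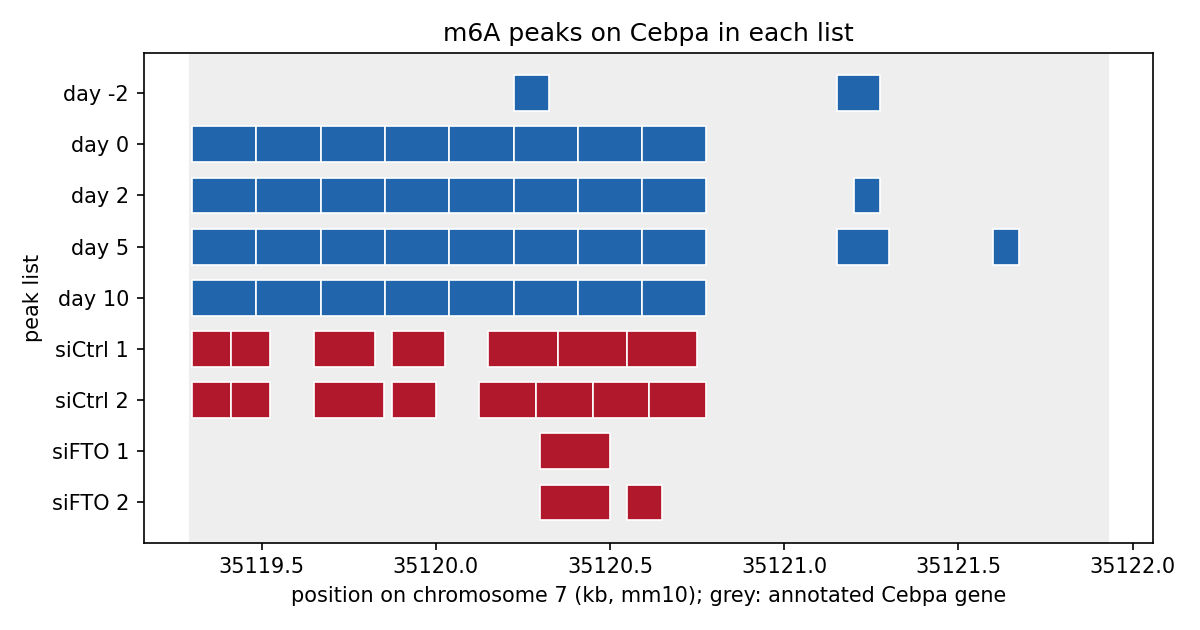
Position of m6A peaks on Cebpa along chromosome 7 (kb, mm10), 1 line per list, with the annotated gene in grey and each box a peak. Peaks tile 1475 bases on day 0 and cover 225 bases on day -2 and 200 and 300 bases in the siFTO lists.

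The remaining lists stayed within the limits. Of 19 m6A writers, erasers and readers in the siRNA lists, 5 had more peaks and 4 fewer (percentile 81.7; 98.4 with equal list lengths), with 57 peaks on day -2. The reader Igf2bp3 (ENSMUSG00000029814) had 1 and 1 against 5 and 5 peaks, the writer subunit Virma 4 and 4 against 7 and 6, and the methyltransferase Mettl3 1 and 1 against 4 and 2. Ythdc2 was gained with 3 and 2 peaks and Hnrnpc with 2 and 1, and Hnrnpa2b1 was lost. The demethylase Alkbh5 (ENSMUSG00000042650) had 13 and 12 peaks in siCtrl, 6 and 4 in siFTO, 2 on day -2 and 10 to 12 on days 0 to 10, and Igf2bp1 had 4 and 4 against 3 and 2. Extracellular matrix genes had fewer peaks in 12 of 25 members and more in 4 (percentile 13.8; 1.32 without matching), with 181 peaks on day -2, and Col3a1 had 34 and 33 against 20 and 19, Col5a1 49 and 49 against 32 and 29, Col6a3 45 and 47 against 32 and 31, and Col6a1 20 and 21 against 18 and 16. Their presence lay at percentile 79.5 (98.6 with equal list lengths).

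Among Wnt, BMP and TGF-beta signalling genes 11 of 25 had fewer peaks and 5 more (percentile 25.5), with 99 peaks on day -2. Wnt6 had 8 and 7 against 2 and 2, Fzd1 16 and 16 against 11 and 10, Fzd2 8 and 8 against 4 and 3, and Dvl1 7 and 8 against 3 and 3, while Gsk3b was gained. Mature adipocyte lipid genes had more peaks in 6 members and fewer in 6 of 22 (percentile 69.7). Fabp5 was gained, with low top folds of 1.85 in siFTO 1 and 1.19 in siFTO 2. Oxidative phosphorylation genes had more peaks in 5 of 15 (percentile 91.3), with Idh3a, Atp5c1 and Uqcrfs1 gained. For markers of macrophages, endothelium and muscle, 4 of 19 genes had a peak in any list, and 1 of them, Des, had fewer peaks in siFTO. On 3 members in the siRNA lists and 2 across stages, their percentiles were 40.3 for presence, 17.2 for peak number and 38.0 for stages. The other 3 marker genes, named after their values were seen, were Csf1r in siCtrl 2 and siFTO 1, Vwf in siFTO 1 and Tek on day -2, each with 1 peak. In presence, adipogenic factors lay at percentile 7.1, inhibitors at 17.6, immediate early genes at 29.1, m6A regulators at 50.6, oxidative phosphorylation genes at 69.1, lipid genes at 80.0 and signalling genes at 88.3.

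The stage lists ask how the m6A pattern differs as preadipocytes become adipocytes. More genes of the mature adipocyte carried peaks after induction. Members of the lipid list with a peak numbered 20 and 18 on days -2 and 0, and 27, 28 and 25 on days 2, 5 and 10. Adipoq, Plin1, Cfd and Cidec had peaks on all 3 late days and on neither early day. Members of the extracellular matrix list with a peak numbered 24 and 24 on the early days and 23, 21 and 22 on the late days. The day -2 list stood apart from the later ones, with a 5' UTR share of 5.90% where days 0, 2, 5 and 10 had 14.0%, 13.3%, 11.9% and 12.5%.

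Lipid genes lay at percentile 99.9 for late against early presence, and at 99.6 without day -2. Plin1 (ENSMUSG00000030546), which coats lipid droplets, had 13, 18 and 16 peaks on days 2, 5 and 10, the highest on day 10 in an intron at chromosome 7, 79723176 to 79723325. Adipoq (ENSMUSG00000022878), the hormone adiponectin, had 3, 7 and 9 peaks, with the highest on day 10 at chromosome 16, 23156451 to 23156575. Cfd (ENSMUSG00000061780), the secreted factor adipsin, had 2, 6 and 6, and Cidec (ENSMUSG00000030278), a lipid droplet protein, 5, 9 and 2. Fabp4, a fatty acid carrier, had 1 peak on day -2, none on day 0 and 2, 7 and 6 later. In all, 7 lipid genes had a peak on each late day and none on day 0, and no lipid gene showed the reverse. Of these 7, Fabp4, Acly and Dgat2 had 1, 5 and 1 peaks on day -2, Acly and Dgat2 being named after their values were seen. These values cannot separate methylation from expression, since a peak needs an expressed transcript.

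Oxidative phosphorylation genes lay at percentile 97.0, inside the limits, at 99.97 without matching and at 98.1 without day -2. Members with a peak numbered 8 and 10 on days -2 and 0 and 15, 14 and 14 on the late days, and Ndufs3 (3, 2 and 2 peaks) had its first on day 2, while Sdha, with a peak on day -2 too, lacked one on day 0. Extracellular matrix genes lay at percentile 2.62, inside the limits, and at 1.09 without day -2. Fn1 (ENSMUSG00000026193), which encodes fibronectin and was named after its values were seen, had 8, 4 and 3 peaks on days -2, 0 and 2 and none on days 5 and 10. Ribosomal protein genes lay at percentile 96.8 with day -2 (99.6 without matching) and 71.5 without it, with 19 members carrying a peak on day -2 and 28 to 31 on the other days, Rpl8 among those appearing on day 2. Splicing factors lay at percentile 95.9, with 25 members on day -2 and 31 to 33 later.

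The other lists lay between percentiles 18.3 and 83.6 across stages. These were adipogenic transcription factors (53.1), inhibitors of adipogenesis (63.6), cell cycle genes (77.8), m6A regulators (27.3), Wnt, BMP and TGF-beta genes (83.6) and immediate early genes (18.3). In the cell cycle list, the replication helicase genes Mcm5 (4, 4 and 4 peaks) and Mcm7 (3, 1 and 2) had peaks on the late days only, and Cdk6 on the early days only. Total peaks on day -2 and then day 0 were 53 and 115 for adipogenic factors, 77 and 160 for inhibitors, 69 and 157 for immediate early genes and 99 and 177 for signalling genes, but 71 and 71 for cell cycle genes. Among the fixed regulators, Pparg had 3, 2, 2, 6 and 4 peaks over the 5 stages, with intronic peaks on days 5 and 10 at 115431426 to 115431500. Runx1t1 had 8, 5, 2, 4 and 3.

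**Figure D3:**
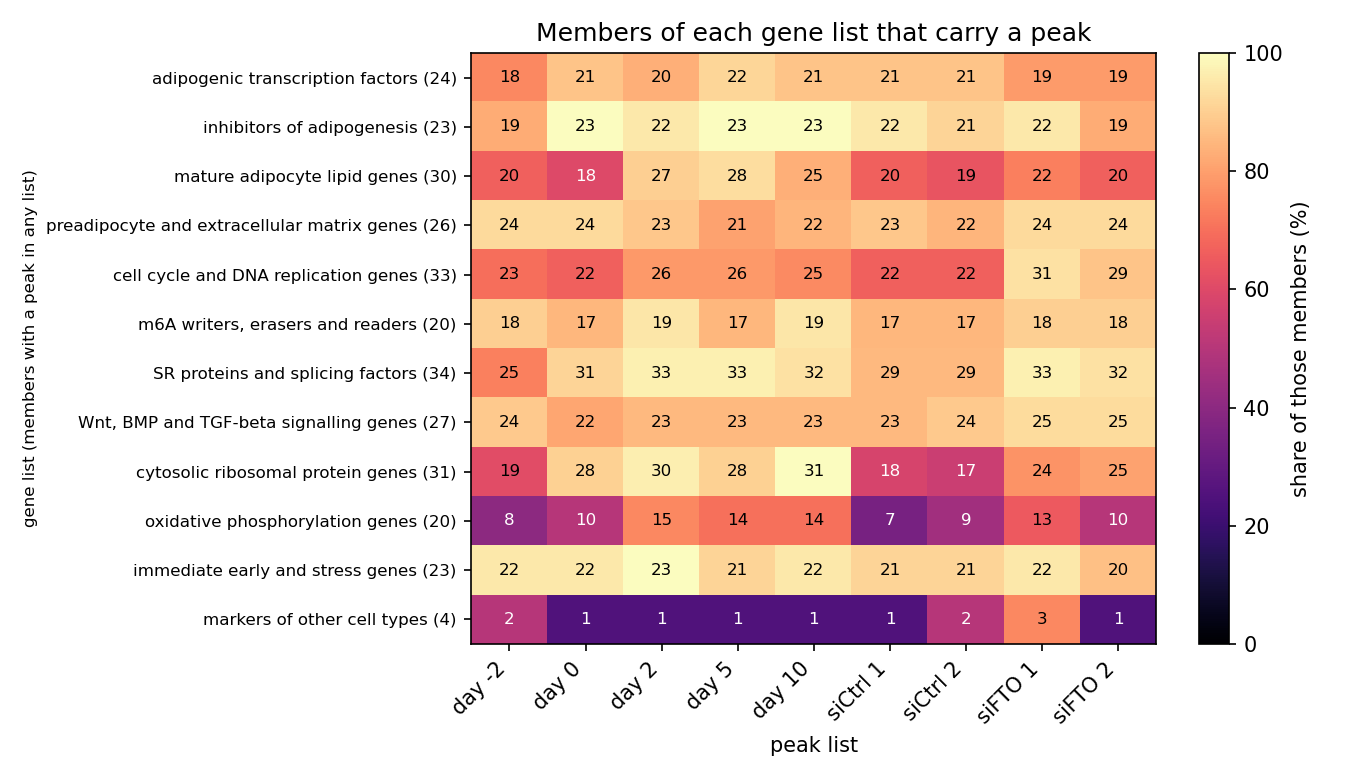
Members of the 12 fixed gene lists that carried a peak in each of the 9 lists; cells give the number, and colour the percent of the members with a peak in any list. Lipid genes number 18 on day 0 and 28 on day 5, and cell cycle genes 22 in each siCtrl list and 31 and 29 in the siFTO lists.

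By region, 9162 were in all 5 stages, and 1808 were on days 2, 5 and 10 only (192 genes) against 239 on days -2 and 0 only (102 genes). Other ways of setting 3 stages against 2 gave 56 to 1111 regions in the 3 and 189 to 1956 in the pair, the 1956 being on days 5 and 10. The day -2 list alone held 10158 regions, and 11473 were in every other stage but not in it, whereas each other stage alone held 1079 to 2267. Jaccard indices of day -2 with later stages were 0.251 to 0.274, and among days 0 to 10 they were 0.659 to 0.738. Without the day -2 list, regions shared by all stages numbered 20635, late genes 415, and early regions and genes 1318 and 217. Keeping the best 26485 peaks of each list by fold gave 5194 shared, 711 late and 416 early regions with 112 late and 195 early genes, and peaks at or above each list's median fold gave 2147 shared and 918 late regions.

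**Figure D4:**
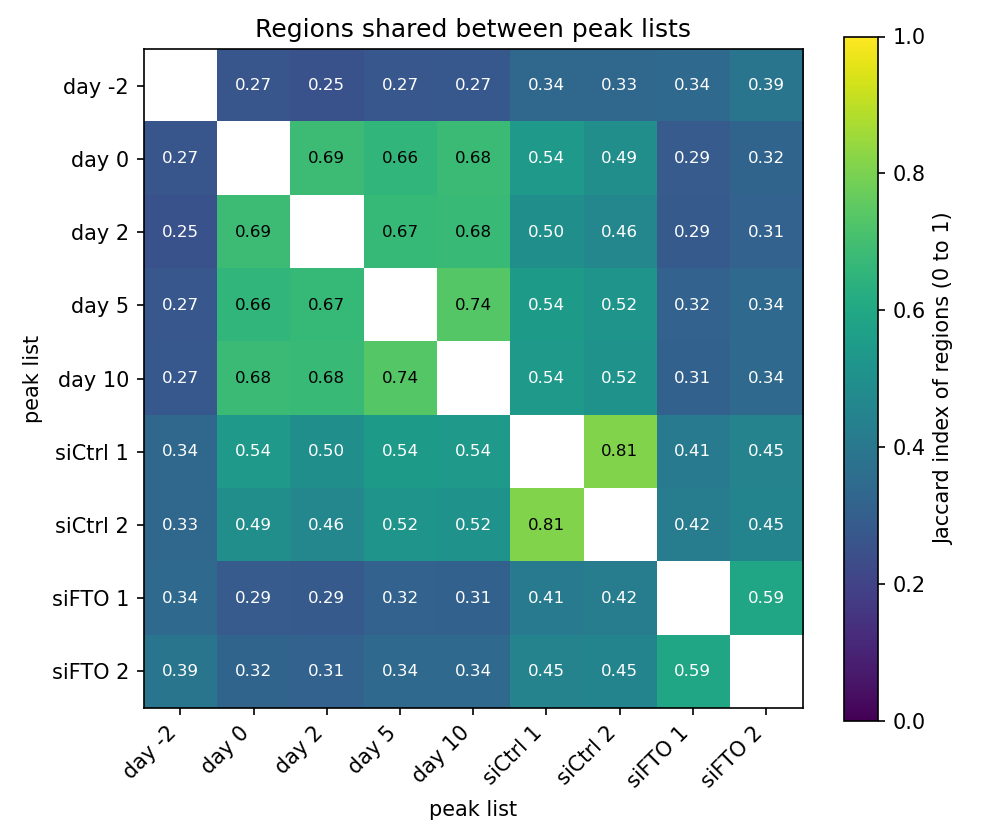
Jaccard index of shared regions for each pair of the 9 lists, from 0 to 1, with both axes listing the stages and then the siRNA lists. Days 0 to 10 pair at 0.659 to 0.738, the siCtrl lists at 0.812, and day -2 at 0.251 to 0.387 with every other list.

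The 10 late genes with the best fold rank were named by the fixed rule, and 8, 10 and 8 of their top folds on days 2, 5 and 10 were evenly spaced. Cdkn1c (ENSMUSG00000037664), a cyclin-dependent kinase inhibitor, had its highest day 2 peak in the coding sequence at chromosome 7, 143459876 to 143460075. Its highest folds were 94.3, 73.6 and 98.6 on days 2, 5 and 10. Gdf5 (ENSMUSG00000038259), a BMP family ligand, had 2, 3 and 3 peaks, the highest on day 2 at chromosome 2, 155944576 to 155944700. Nog (ENSMUSG00000048616), the BMP antagonist noggin, had 5, 1 and 4 peaks, the highest on day 2 in the 5' UTR at chromosome 11, 89302039 to 89302150. Ppp1r1b (ENSMUSG00000061718), a protein phosphatase inhibitor, had 6, 7 and 1 peaks, with a top day 2 fold of 399 at chromosome 11, 98348726 to 98348875. The others were Syngr4, Il17re, Lag3, Cisd3, Itpka and Kcnt1, and 6 of the 10 had no peak in any siRNA list.

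The 10 early genes named likewise had mostly intronic top peaks, and all their top folds on days -2 and 0 were evenly spaced. Positions are those of the top day -2 peak, and each fold is the gene's highest on its day. Ifit2 (ENSMUSG00000045932), an interferon-induced gene, had 4 and 1 peaks on days -2 and 0, the highest at chromosome 19, 34551476 to 34551600, with folds of 677 and 188. Ercc8 (ENSMUSG00000021694), a DNA repair gene, had 2 and 1 peaks, the highest at chromosome 13, 108183151 to 108183275. Rasal2 (ENSMUSG00000070565), a Ras GTPase activator, had 1 and 2 peaks. The highest was in the 3' UTR at chromosome 1, 157139351 to 157139475, on day -2 and in the 5' UTR on day 0. Grid2ip and Elp4 had no peak in the siRNA lists, and Ntm, Rab3c, Kcnj6, Cpa6 and Abca8b had peaks in 1 or both siFTO lists, as did Ifit2, Ercc8 and Rasal2. Abca8b was the one early gene of the 10 with peaks in siCtrl, 2 and 3.

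Of the 10 genes with the best fold rank in all 9 lists, 6 had their highest peak in the same transcript part in every list. Klk14 (ENSMUSG00000044737), a kallikrein protease, had 1 peak in each list, in the 3' UTR at chromosome 7, 43695101 to 43695225 on day -2, and ranked at or above percentile 99.6 of the folds in every list. Purb (ENSMUSG00000094483), a nucleic acid binding protein, had its highest peak in the 5' UTR in all 9 lists, on day -2 at chromosome 11, 6475851 to 6475975. Marcks (ENSMUSG00000069662), a substrate of protein kinase C, had its highest in the coding sequence in all 9, on day -2 at chromosome 10, 37136370 to 37136563, and Cfap46 in the 3' UTR. Olfm1 and Slc36a2 had theirs in an intron in all 9. For Maf, Snx9, Basp1 and Arhgap23 the part differed between lists, and the highest peak of Snx9 and Arhgap23 was intronic on day -2 and in both siFTO lists, as was that of Snx9 in both siCtrl lists.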

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

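All tests in this part were chosen after the results they bear on were seen. Peaks on mitochondrial transcripts lie outside the comparisons of the report, because their lines carry no fold. They numbered 12 in siFTO 1 and 13 in siFTO 2, against 2 in each siCtrl list, and 21 on day -2, against none on days 0 to 10. The siFTO peaks lay on 10 genes in each list, among them mt-Nd5 with 3 and 4 peaks, and the day -2 peaks on 9, with 5 on mt-Nd5. These stood above the level of the control lists, and no explanation was tested.

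The first pattern is the scarcity of 5' UTR peaks in siFTO. A change in which genes carry peaks was argued against, since among the genes with a peak in all 9 lists the difference was -5.87 points, close to the -6.88 over all genes. The scarcity was not confined to peaks of low fold, because peaks at or above each list's median fold differed by -9.56 points. This cut cannot test thinly covered peaks, since fold does not measure coverage. It also acts unequally on the groups. In siFTO, 5' UTR peaks had median folds of 3.21 and 3.49, below the list medians of 4.09 and 4.06. In siCtrl they had 3.95 and 3.92, above the list medians of 3.45 and 3.49. A library property shared with day -2 may contribute, since that list, made without knockdown, had a 5' UTR share of 5.90%, under the lowest share among days 0 to 10 and siCtrl, 11.2%. Fto knockdown and such a property cannot be told apart here, because the 2 conditions differ in library as well as in treatment and the list at 5.90% has no replicate.

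The second pattern is the set of regions gained or lost in both siFTO lists. Input reads at their floor would give folds on whole multiples of one value and may contribute to the gained set, though no input counts were available. Of the siFTO peaks in gained regions, 16.2% lay on such folds (95% interval 15.6 to 16.9), against 2.81% (2.65 to 2.97) in regions of all 4 siRNA lists. The spacing was chosen on intronic folds, and 24.6% of gained regions were intronic against 8.87% of regions in all 4 lists. Part of the gap may follow from that. The intervals treat the peaks of both siFTO lists as independent, though each gained region has peaks in both. Without such peaks there were 4779 gained regions and 743 gained genes, against 5890 and 992 with them, and input reads that are few but above the floor were not tested. A library property shared with day -2 could contribute to both sets, since day -2 held 36.1% of the gained regions, above the 18.2% of the highest later stage, and 15.5% of the lost regions, below the 67.6% of the lowest. A biological effect of the knockdown stays open as well, and GC content and depth were not tested.

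The third pattern is the distance of the day -2 list from the other stages. Its shorter list was argued against, because at equal list lengths its highest Jaccard index with another stage was 0.216, against a lowest value of 0.550 among days 0 to 10. A change at an even pace with time was argued against too, since the index of day -2 with day 0, at 0.268, lay below the lowest among days 0 to 10, 0.659, by more than the gap of 0.222 between the siCtrl pair and the siFTO pair, whereas a change confined to the days before day 0 stays open. A library property shared with siFTO may contribute, as both siFTO lists held 24.8% of the regions missing on day -2 where both siCtrl lists held 59.7%, and 26.7% of the regions of day -2 alone where siCtrl held 12.7%. Over all regions the day -2 list lay little nearer to siFTO 1 than to siCtrl. Its Jaccard index was 0.343 with siFTO 1 and 0.387 with siFTO 2, against 0.337 and 0.335 with siCtrl 1 and 2. The stage itself stays open as a biological explanation, untested with 1 library, since day -2 precedes induction.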

How the results depend on the processing

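The tests on 5' UTR and intron shares, on counts of genes other than presence per gene, on gene lists by peak number or with equal list lengths, without day -2, without what day -2 shares with siFTO and without evenly spaced folds were chosen after the results were seen; the others were planned. Of the alternatives to the results that answer a comparison, 91 kept the result, 27 moved it (a count by more than a factor of 1.5) and 1 reversed it. Differences between groups, with the Jaccard difference, were judged by their sign alone. An intron difference of 2.44 in place of 6.96 therefore counted as kept. With the replicate block, peak number (-2188.5) and gained and lost regions (5890 and 6949) equalled the main values by construction. The same holds for gained and lost genes and for the 5' UTR, 3' UTR and intron differences (-6.88, 1.36 and 6.96). None of these tests the pairing, though they count among the 91. Where the block could differ, it gave 0.273 for the Jaccard difference and 2622 and 2937 genes with more and fewer peaks, changing no call. By number, siFTO minus siCtrl peaks were 3497 for replicate 1 and -7874 for replicate 2. The labels do not say that same-numbered samples were made together, though both second samples are marked rep2. The correlation between same-numbered lists in their deviations from the group means was -0.00278 over regions. Leaving out each replicate in turn gave these ranges: peak number -6297 to 1920 (reversed without siFTO replicate 2), gained regions 6318 to 14286, lost regions 7908 to 9128, gained genes 1106 to 1796, lost genes 553 to 974, genes with more peaks 2692 to 4725 and with fewer 3034 to 4153, Jaccard difference 0.154 to 0.398, and 5' UTR, 3' UTR and intron differences -7.22 to -6.54, 0.626 to 2.10 and 5.79 to 8.12. The intron difference was 2.44 without evenly spaced folds and 13.3 at or above the median fold, and without evenly spaced folds there were 4779 gained regions and 743 gained genes. The spacing was chosen on intronic folds, so leaving out these folds takes away intronic peaks by preference. Counts rise by construction where fewer lists must hold or lack a region. Presence per gene gave 992 gained, 499 lost, 192 late and 102 early, by construction fewer than regions. An overlap of 50% of each peak gave 12077 lost regions, and the cause was not tested. Leaving out what day -2 shares with siFTO gave 3761 gained and 1078 lost regions and 436 gained and 171 lost genes. Peaks at or above the median fold gave 818 lost genes, 2147 regions in all stages and 918 late regions, and equal list lengths gave 5194 in all stages, 711 late and 416 early regions, and 112 late and 195 early genes; the cause was not tested. Without the day -2 list there were 20635 regions in all stages, 1318 early regions, 415 late genes and 217 early genes, where the rule asks for one list less. The ratio of day 10 to day -2 peaks was 1.68 with all peaks. Peaks at or above the median fold also gave 1.68, but that cut keeps nearly the same share of each list. It therefore nearly fixes this ratio and the sign of the peak number difference, and tests neither. Of the gene list percentiles, 52 alternatives kept the side of the limits, 10 passed them newly and 4 no longer did. The exon junction result and the motif results (RRACH against GGAC, and both windows) were not run, because no genome sequence was used. Equal list lengths were not run for peak number or the ratio, which they fix. With depth unknown, regions absent from a list were not detected there, which does not show that they lack m6A.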

Other observations

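The tests in this part were chosen after the results were seen, and the values are given without explanation. Ribosomal protein genes held some of the highest folds of the later stage lists. Members with a top fold in the highest 1% of their own list numbered 7, 11, 9 and 11 on days 0, 2, 5 and 10, and 0 on day -2 and in all 4 siRNA lists. Rpsa (ENSMUSG00000032518), a component of the small subunit, had 3, 4, 4 and 4 peaks on days 0, 2, 5 and 10, 2 on day -2 and 3 in each siRNA list. Rpl19 (ENSMUSG00000017404) had 6 peaks on each of days 0 to 10, 3 on day -2, 4 and 4 in siCtrl and 4 and 5 in siFTO. Rps6 had 6 peaks on each of days 0 to 10 and none on day -2. These genes were chosen after their values were seen.

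Immediate early genes had 3, 3, 7 and 7 members in the highest 1% on days 0, 2, 5 and 10, 0 on day -2, and 1, 0, 1 and 1 in the siRNA lists. Fosb (ENSMUSG00000003545), an AP-1 subunit, had 12, 16, 16 and 18 peaks on days 0 to 10, 6 on day -2, 8 and 5 in siCtrl and 4 and 1 in siFTO. Ppargc1a had 5 and 3 peaks in siCtrl, 3 and 2 in siFTO and none in any stage list. Klf15, an adipogenic factor, had 4 and 2 peaks on days 5 and 10 and none in any other list, and Retn, the hormone resistin, had 5 and 6 on days 5 and 10 alone. All of these genes were chosen after their values were seen.

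Peaks that began where the gene's previous peak ended made up 25.3%, 24.2%, 25.8% and 25.1% of peaks on days 0, 2, 5 and 10. The share was 22.9% and 23.3% in siCtrl, but 7.26% on day -2 and 12.3% and 10.1% in siFTO. The first peak of each run, as on Cebpa, is not counted. Runs of 4 or more adjoining peaks numbered 33 on day -2, 118 and 65 in siFTO, 417 and 441 in siCtrl and 592 to 751 on days 0 to 10. Within the day -2 list intronic peaks had a median fold of 22.1 and coding peaks one of 4.29. Of intronic folds above 5, 49.9% on day -2 were whole multiples of one value, against 24.8% to 35.0% on days 0 to 10.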
